A study of Aspergillus oryzae RIB40 with 6 samples.

How the data were processed

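RNA-seq libraries of Aspergillus oryzae RIB40 hyphae were compared between liquid culture (3 libraries) and solid wheat bran culture (3 libraries). Per the labels' protocols, DNase-treated total RNA was purified, 2 ug went into a stranded mRNA library kit, and paired 101 bp reads were taken on an Illumina HiSeq instrument. The submitters' processing notes list bcl2fastq 1.8.3, cutadapt 1.1, Trimmomatic 0.32, TopHat2 2.1.1, Cufflinks 2.2.1, HTSeq 0.7.2 and edgeR 3.20.9, without roles or order. The genome build, the annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Values of near-identical gene copies and of overlapping or antisense genes are therefore uncertain. The series' design text calls the replicates biological, and nothing says whether they were separate flasks or days, so p-values measure the spread between these libraries.

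The deposited count tables hold whole-number counts per gene for 12364 gene IDs, 1 table per library, as raw counts with no rows for unassigned reads. The deposited FPKM table holds 1 FPKM value per gene and library, normalized by the authors for gene length and library size. Total counts per library ran from 18129454 to 19815758. Of the gene IDs, 11781 matched a locus tag of the ASM18445v3 gene table, 583 did not, and 708 of those matched had a symbol. The table was used for symbols, gene order and gene lengths only, and no coordinates are printed because the authors' build is not named. The table gives no strand.

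Genes were tested with edgeR 4.0.16 in R 4.3.3 with a quasi-likelihood F test (glmQLFit and glmQLFTest, robust), TMM scaling and the filterByExpr filter, which kept 10546 genes. Calls are Benjamini-Hochberg adjusted p under 0.05 over those genes. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.2. CPM values are scaled by TMM. Ratios of genes with 1 to 3 counts in a culture carry 95% exact counting intervals. Counts of reads are not counts of independent molecules, so intervals and limits cover counting error only. Single values per library were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. No pair of libraries was a duplicate: the chi-square per degree of freedom between replicates was 38.4 to 101.

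Gene lists were planned by product text and remembered locus tags before the data were examined, but the gene table has symbols alone. Of 31 planned lists only heat shock proteins matched 5 or more symbols, remembered tags were not used, and so planned lists such as starch degradation and nitrate assimilation are not reported here. In their place, 29 lists of symbols were written after the symbols had been seen and before any expression value was compared. They hold only genes that carry a symbol. The 25 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over those lists. Camera with an estimated correlation and fry were alternatives. Of the calls, neither list that passed with the preset correlation passed with an estimated one.

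A rule for named genes was fixed beforehand, but it asked for a product description and, without any, allowed only a few IDs in each direction. As the gene table has symbols alone, a symbol stood in for the description, which changed the rule. It then took the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, a mean of at least 10 CPM and no overlap between the cultures' libraries. It added the 5 genes of highest mean CPM in each culture, and up to 4 called members of each list with the largest change and at least 10 CPM. Members that the rule would have named by remembered tags were left out. Outside the rule, hapX, sreA, sidC, sidD, xlnR, pgxC, plyC, pgxB, abfI, sdh2, gliK, dbp3, cia1, erg12 and AO090701000867 were named after their values had been seen, and the 8 iron-sulphur enzymes were named for the test of iron supply. Their values had been computed when that test was written, so it counts as chosen after. Their p was adjusted together with the 25 lists, and this adjustment was chosen after the unadjusted p had been seen.

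Neighbouring genes were the next tested genes on the same chromosome in the ASM18445v3 table, and gene order was permuted 1000 times within chromosomes with a fixed seed. The test was checked on simulated data: with counts drawn for 10546 genes at the real means and library sizes, and 200 changed genes, edgeR called 52% of the 2-fold and 93% of the 4-fold changed genes, and 6.45% of calls fell on unchanged genes (10443 genes tested, solid against liquid). With so few changed genes the adjusted threshold is stricter than in the real fit, so these shares do not carry over to it. Alternatives were other scalings (DESeq2 1.42.0 size factors, library size alone, TMM without the 50 most abundant genes), no filter, a filter of 10 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, limma-trend on log2(FPKM + 1), a threshold of 2-fold, glmTreat against 2-fold, the replicate number as a block, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.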

Results

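Aspergillus oryzae is the filamentous fungus of sake, miso and soy sauce fermentation, and RIB40 is the wild-type strain used here. Polyadenylated RNA was sequenced from hyphae of 2 cultures, each kept for 48 h at 30 °C, with 3 replicate libraries per culture. The liquid culture was 50 mL of Czapek-Dox medium, labelled CD-Glc for its glucose and otherwise a defined salts medium, shaken at 200 rpm. The solid culture was 2.8 g of wheat bran wetted with 2.2 mL of water, left standing for 20 h, mixed once and left standing for another 28 h. The total counts ran from 18129454 to 19815758 per library, so that 3 counts, the limit that a count of 0 allows, correspond to between 0.146 and 0.182 CPM, a gene's counts scaled to a common library total with TMM factors, for counting error only. The series title concerns DNA methylation in this fungus. Methylation was not analysed here, and the comparison asks how transcript levels differed between the cultures. Medium, shaking and the solid surface differed together, so each difference belongs to the whole culture.

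Of the genes for siderophores, the small molecules with which fungi take up iron, and for iron uptake, 12 of 13 were lower in solid culture, while 9 of 12 genes for asexual sporulation and 13 of 18 for the breakdown of plant cell walls were higher. As lists, the first and the last passed in limma's camera with a preset correlation and not with an estimated one. At the preset, splits of the libraries that mix the cultures moved up to 7 lists, so these list calls alone are weak support. The siderophore synthesis gene sidI (AO090023000529) had 291 ± 82.6 CPM in liquid and 0.0852 ± 0.0625 CPM in solid culture (mean ± SD, n = 3), and fell by 11.66 ± 0.42 on the log2 scale (± SE, edgeR adjusted p = 6.83e-07). It had only 5 counts over the solid libraries, against 15663 over the liquid ones, so the size of its fall is uncertain. The central conidiation regulator brlA (AO090005001041) rose from 6.4 ± 0.365 to 335 ± 19.9 CPM, a log2 fold change of 5.71 ± 0.14 (edgeR adjusted p = 2.59e-07). The cellobiohydrolase gene cbhC (AO090038000439) rose from 0.219 ± 0.14 to 83.9 ± 25.8 CPM, by 8.52 ± 0.40 on the log2 scale (edgeR adjusted p = 1.99e-06). It had only 12 counts over the liquid libraries, against 4977 over the solid ones, so the size of its rise is uncertain too.

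Over the whole transcriptome, 6204 of 10546 tested genes changed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 3248 higher and 2956 lower in solid culture. With so many calls, a gene list whose shares of higher and lower members lie near these is not set apart by its counts. Of the genes that changed, 4033 did so by at least 2-fold in the fitted value, 2390 higher and 1643 lower. Scaling by library size alone gave 3926 higher and 2286 lower, so that 63.2% of the calls were higher against 52.4% with the main scaling. In limma-trend, the authors' values as log2(FPKM + 1) gave 3992 higher and 2293 lower (63.5%). Those settings moved the median log2 fold change of all tested genes from 0.02 to 0.20 and 0.18, and fold changes below are relative to the main scaling. The first principal component of log2 CPM separated the cultures and held 93.5% of the variance. Correlations of log2 CPM across genes, which are not independent replicates, were 0.981 to 0.992 within a culture and 0.744 to 0.768 between cultures.

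Of the 13 tested genes of the siderophore and iron list, 12 fell and 0 rose in edgeR, DESeq2 and limma-voom, also at an unadjusted edgeR p under 0.05, with a median log2 fold change of -5.05. The list moved against the other genes in camera (adjusted p = 2.25e-06 over 25 lists), and the call was lost with an estimated correlation (adjusted p = 0.727 with an estimated correlation, and 5.45e-08 to 0.727 over all alternatives). The transporter genes mirB, mirD and sit1 fell, with log2 fold changes of -8.83 ± 0.51, -6.80 ± 0.26 and -6.36 ± 0.36. For mirB the size is uncertain, with only 20 counts over the solid libraries. The gene sidJ, named after a siderophore esterase gene, and the siderophore synthesis gene sidH fell, with log2 fold changes of -6.47 ± 0.27 and -6.38 ± 0.33. The regulator hapX, which is induced when iron is short, fell by 2.66 ± 0.16 (edgeR adjusted p = 6.1e-06), and sidC had a log2 fold change of -1.53 ± 0.26 (edgeR adjusted p = 0.00158). The exception was sreA, the repressor of iron uptake, at 127 ± 16.2 CPM in liquid and 143 ± 1.47 CPM in solid culture (edgeR adjusted p = 0.276), which passed as higher with library-size scaling alone.

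Among 9 regulators of asexual development, 6 rose and 1 fell. The rises ran from 0.59 ± 0.12 to 5.71 ± 0.14 on the log2 scale. Regulators were listed whether they promote or repress sporulation, so the count is not one of activators. Beside brlA, flbD rose by 2.83 ± 0.20 and vosA by 1.41 ± 0.23 on the log2 scale, while medA fell by 1.51 ± 0.17 (edgeR adjusted p = 0.000144). The list did not pass in camera (adjusted p = 0.198, and 0.000702 to 0.727 over all alternatives) and passed only in fry, which asks whether a list's genes move 1 way without comparing them with other genes. All 3 genes listed for conidial pigment and spore catalase rose: ayg1 by 5.93 ± 0.28, the spore catalase gene catA by 4.01 ± 0.18 and the pigment polyketide synthase gene pksP by 2.99 ± 0.16. That list is too short for a list test. The values of each library are plotted for these genes and the iron genes.

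**Figure D1:**
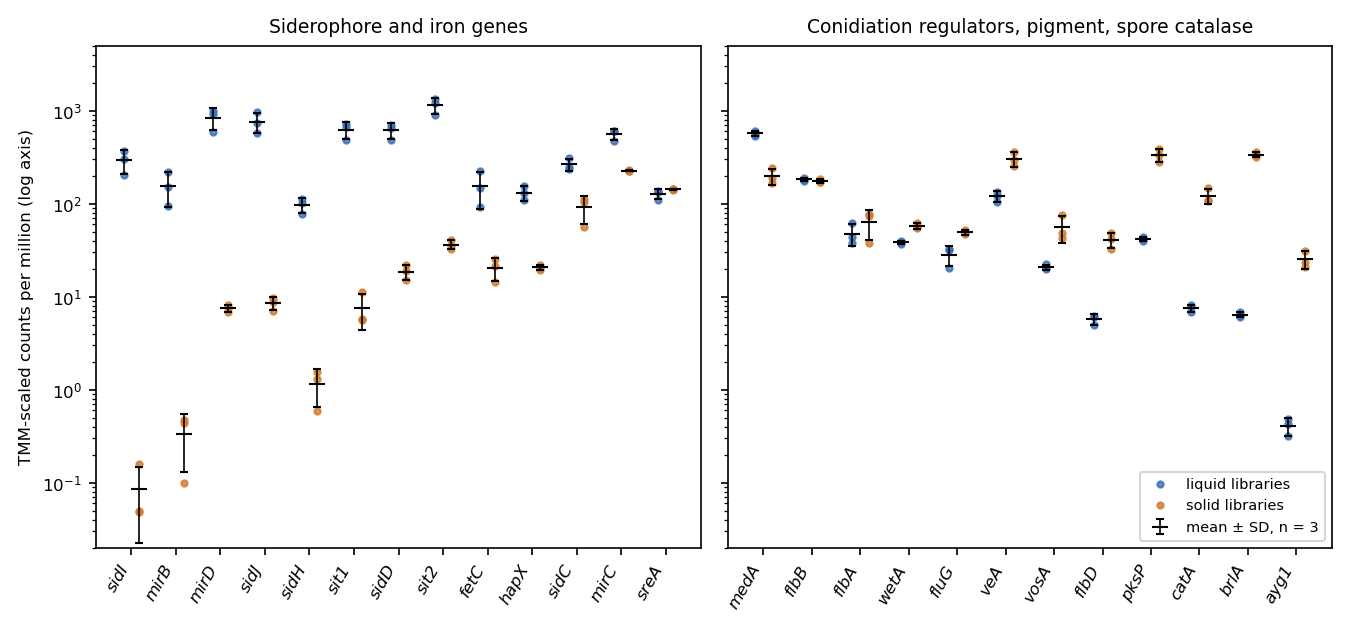
CPM after TMM scaling on a log axis for each gene of the siderophore and iron list (left) and of both conidiation lists (right), with 1 point per library and bars for mean ± SD (n = 3). Of the iron genes, sidI has the lowest mean in solid culture, at 0.0852 CPM (5 counts over the solid libraries) against 291 CPM in liquid, and brlA has 6.4 CPM in liquid and 335 CPM in solid culture.

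Of 18 genes for the breakdown of plant cell wall polysaccharides, 13 rose and 3 fell, with a median log2 fold change of 4.14, or 3.79 with abfI, which had 2 counts in the liquid libraries, at the lower bound of its counting interval. The list moved in camera (adjusted p = 0.013), and the call was lost with an estimated correlation (adjusted p = 0.727 with an estimated correlation, and 0.000855 to 0.727 over all alternatives). After cbhC, the endoglucanase gene eglD rose by 8.02 ± 0.56, the feruloyl esterase gene faeB-1 by 6.12 ± 0.51 and the beta-xylosidase gene xlnD by 5.58 ± 0.36 on the log2 scale. The 3 that fell were pgxB, pgxC and plyC, with log2 fold changes of -1.51 ± 0.19, -1.17 ± 0.22 and -1.05 ± 0.33. The xylanase regulator gene xlnR had 72.7 ± 11.4 CPM in liquid and 84.5 ± 17.3 CPM in solid culture (edgeR adjusted p = 0.356).

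Genes of the fungal cell wall moved both ways: 6 of 27 rose and 15 fell, with a median log2 fold change of -0.51 and a mean of -0.02, and the list did not pass in camera (adjusted p = 0.121). The chitinase gene chi3 had 1 count over the liquid libraries and 12643 over the solid libraries, a scaled ratio of 11420 with a 95% counting interval of 2049 to 451000. Another chitinase gene, chiA1, fell by 4.57 ± 0.26 (497 ± 47.1 to 20.9 ± 6.26 CPM, edgeR adjusted p = 4.05e-06). The glucanase gene exg1 rose by 3.97 ± 0.22 and the alpha-glucan synthase gene ags2 by 3.47 ± 0.31.

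**Figure D2:**
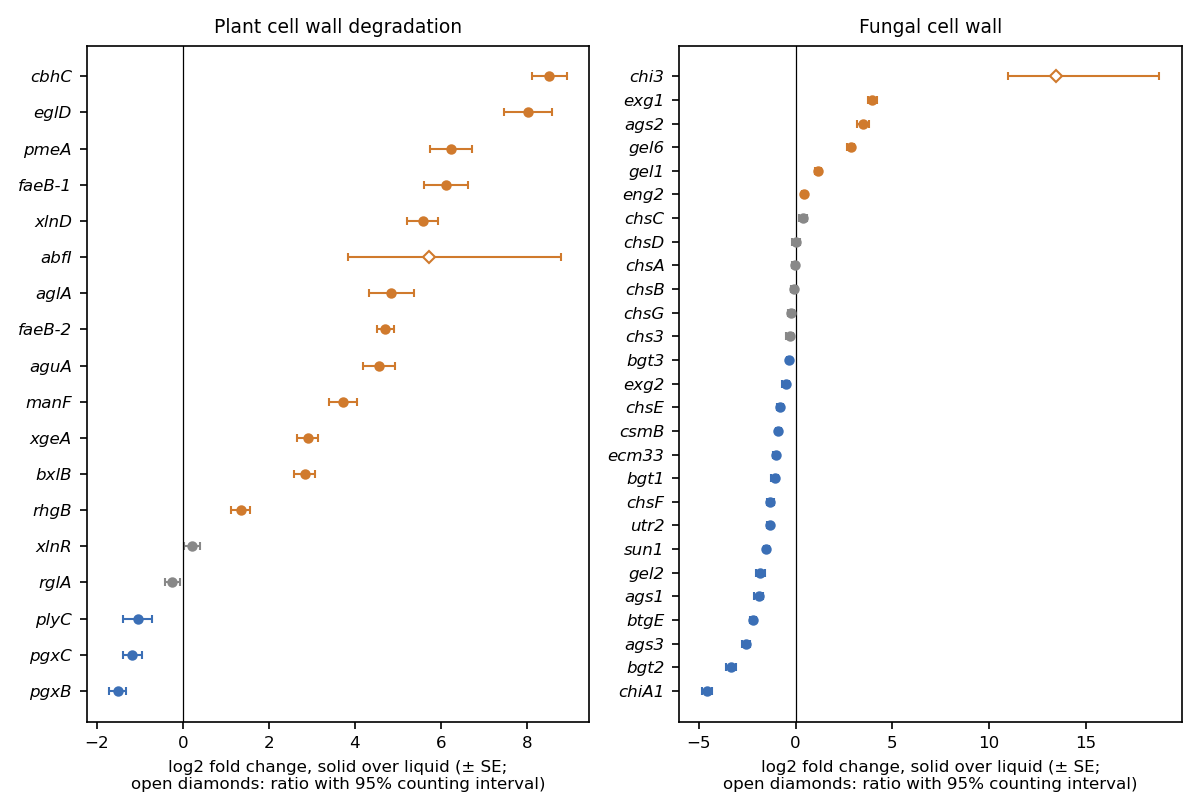
Log2 fold change, solid over liquid, with its standard error for each gene of the plant cell wall degradation list (left) and the fungal cell wall list (right). Orange marks genes higher and blue genes lower in solid culture in edgeR's test, grey marks genes that did not pass, and open diamonds give ratios with 95% counting intervals for abfI and chi3, which had 2 counts and 1 count in liquid culture. In the left panel 13 of 18 genes are higher, and in the right panel 6 of 27 are higher and 15 lower.

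In central carbon metabolism, 4 of 7 glycolysis and tricarboxylic acid cycle genes fell and 1, sdh2, rose (camera adjusted p = 0.216). The glycolytic genes gpdA and pgkA each fell, with log2 fold changes of -2.01 ± 0.16 and -2.01 ± 0.21, the citrate synthase gene cit1 fell by 1.20 ± 0.25 and the glucokinase gene glkA fell by 0.97 ± 0.12. Of 5 genes for gluconeogenesis and acetate use, 3 rose and 1 fell, or 3 and 0 with library-size scaling (camera adjusted p = 0.754). The phosphoenolpyruvate carboxykinase gene acuF rose by 1.95 ± 0.45 and the acetate regulator gene facB by 1.06 ± 0.17. Of 20 amino acid biosynthesis genes, 7 rose and 10 fell, with a median log2 fold change of -0.44 against a mean of 0.12 (camera adjusted p = 0.823, direction down, with fry's direction up). The lysine and methionine genes lys1 and met16 fell, from 540 ± 197 to 155 ± 9.1 CPM and from 148 ± 27.2 to 44.5 ± 7.25 CPM, and the branched-chain genes ilv3 and ilv3B rose by 2.08 ± 0.13 and 1.85 ± 0.22 on the log2 scale. All 4 genes for phenylalanine and tyrosine breakdown rose, from hmgX at 1.58 ± 0.16 to maiA at 2.27 ± 0.13. Of 4 oligopeptide transporter genes 3 rose, with optB at 3.03 ± 0.28, both lists being too short for a list test. Of 6 peptidase genes 1, cps1, rose by 2.97 ± 0.30 (camera adjusted p = 0.823).

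Heat shock proteins and co-chaperones included 6 of 10 genes that fell and 0 that rose in edgeR, DESeq2 and limma-voom, also at an unadjusted edgeR p under 0.05. The mitochondrial chaperone gene hsp78 fell by 2.56 ± 0.35 on the log2 scale and hsp60 from 1224 ± 417 to 351 ± 40.6 CPM. The cochaperone gene fes1 fell by 1.97 ± 0.22 and hsp90 fell by 1.45 ± 0.34. The list did not pass in camera (adjusted p = 0.121) but passed without the second liquid library (adjusted p = 0.0157, with a range of 0.0157 to 0.959 over all alternatives), in which hsp90 was lowest of the liquid libraries at 3281 CPM. The shorter list written before the data were examined, of 5 hsp genes, had 4 lower and 0 higher, also adjusted over the list alone, and gave a camera p of 0.0264 as the only list so tested, or a p of 0.278 with an estimated correlation. In endoplasmic reticulum folding and early secretion, 7 of 19 genes fell, 5 adjusted over the list alone, and 1, the protein disulfide isomerase gene pdiA, rose by 0.67 ± 0.15 (camera adjusted p = 0.439). Scaling by library size alone left 1 of these lower and 2 higher.

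Of 16 ergosterol biosynthesis genes, 3 rose and 6 fell, with a median log2 fold change of -0.07 and a mean of 0.19 (camera adjusted p = 0.823). The sterol desaturase gene erg5 rose by 6.30 ± 0.20 and erg4A by 2.86 ± 0.17, and the squalene epoxidase gene erg1 fell by 2.36 ± 0.28 and erg8 fell by 2.04 ± 0.26. In oxidative stress defence, 3 of 8 genes rose and 3 fell, with a median log2 fold change of -0.05 and a mean of 0.60 (camera adjusted p = 0.947). The superoxide dismutase gene sod1 rose by 2.18 ± 0.26 and the catalase gene cat1 by 2.05 ± 0.26, beside catA, which stands in this list too, while the regulator yap1 fell by 1.55 ± 0.13.

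The remaining lists passed no camera test, and brackets give their camera adjusted p. Several of their counts moved when libraries were scaled by size alone, and these are given beside the main counts. Of 27 ribosome biogenesis genes 5 rose and 2 fell (0.634), 0 and 2 adjusted over the list alone, and 15 were higher with library-size scaling. Of 5 cytosolic ribosomal protein genes 1, rps1, rose by 0.45 ± 0.12 on the log2 scale (0.474), and all 5 were higher with library-size scaling. Of 5 translation initiation factor genes 2 rose (0.65), 1 adjusted over the list alone, and 3 were higher with library-size scaling. Of 24 chromatin and histone modification genes 4 rose, among them the histone chaperone genes rtt106 by 0.82 ± 0.16 and asf1 by 0.62 ± 0.11, and 1, spt6, fell (0.941), or 4 and 0 adjusted over the list alone and 7 and 0 with library-size scaling. Of 17 replication, repair and mitosis genes 5 rose and 7 fell (0.754), or 6 and 3 with library-size scaling. Of 12 peroxin genes 1 rose and 5 fell (0.439), or 1 and 4 both adjusted over the list alone and with library-size scaling. Of 5 septin genes 3 fell (0.64), or 0 with library-size scaling, which had 1 higher. Of 5 autophagy genes 1 rose and 1 fell (0.943), or 0 and 1 adjusted over the list alone and 2 and 1 with library-size scaling, and of 4 zinc transporter genes, too few for a list test, 1 rose and 2 fell, or 1 and 1. The proteasome gene pup1 fell by 0.29 ± 0.11, alone among 16 (0.943), and tom70 fell by 0.41 ± 0.15, alone among 10 genes for mitochondrial import and organisation (0.754). Neither passed when adjusted over the list alone or with library-size scaling, where 2 proteasome and 3 mitochondrial genes were higher. At an unadjusted edgeR p under 0.05, 6 of the mitochondrial genes were lower and 1 higher, and in DESeq2 2 were lower and 0 higher. Of 12 splicing genes 0 passed in edgeR or limma-voom, 1 was lower in DESeq2, 2 were higher with library-size scaling, and at an unadjusted edgeR p under 0.05 there were 1 higher and 1 lower (0.998).

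**Figure D3:**
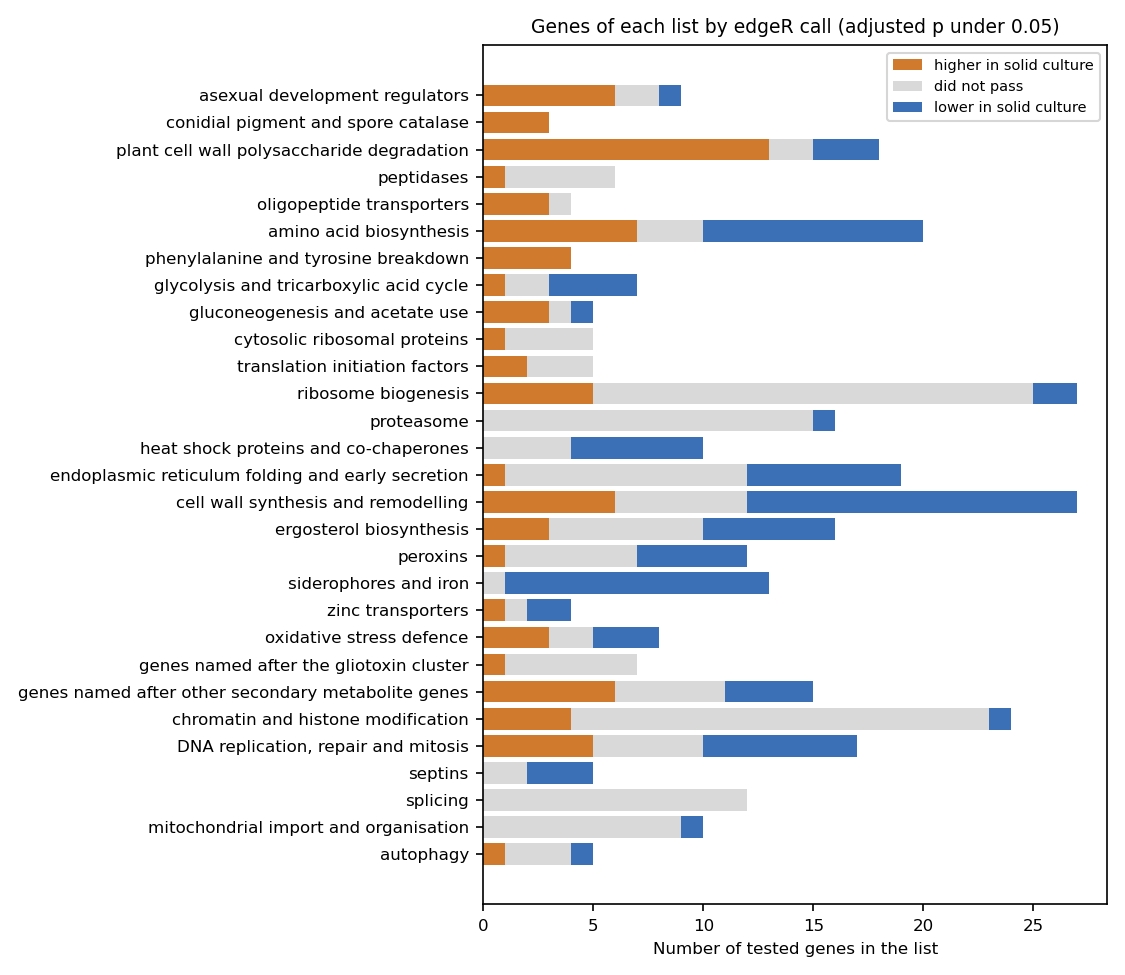
Number of tested genes in each of 29 lists that were higher in solid culture (orange), lower (blue) or did not pass (grey) in edgeR's test at an adjusted p under 0.05. The siderophore and iron list holds 12 lower genes of 13 and the plant cell wall degradation list 13 higher genes of 18.

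Among genes with a symbol, outside these lists and at a mean of at least 10 CPM, those with the largest changes included aspf1, named after a ribotoxin and allergen gene, which rose by 8.42 ± 0.41 on the log2 scale, and gta1, which rose by 6.84 ± 0.37. AfusinC had 2 counts over the liquid and 1268 over the solid libraries, a ratio of 572.5 with a 95% counting interval of 158.2 to 4733. The flavohemoglobin gene fhpA fell by 6.11 ± 0.27, from 2557 ± 457 to 37 ± 9.88 CPM (edgeR adjusted p = 1.58e-06), and the fumarate reductase gene frdA fell by 5.59 ± 0.43. The 5 most abundant genes of each culture made 9 genes, of which 2 rose, 4 fell and 3 did not pass. AO090020000588 rose from 0.791 ± 0.368 to 7243 ± 683 CPM and AO090012000143 from 341 ± 42.9 to 7994 ± 872 CPM. AO090701001051 fell from 5848 ± 383 to 5.83 ± 4.36 CPM and AO090010000644 from 6604 ± 1451 to 47.6 ± 3.1 CPM. The glutamine synthetase gene glnA fell by 1.11 ± 0.18 and AO090020000403 by 1.22 ± 0.18 on the log2 scale. AO090120000080, the most abundant in liquid culture, had 9854 ± 316 CPM there and 8598 ± 822 CPM in solid culture (edgeR adjusted p = 0.215), and the other 2 were ribosomal RNA rows (edgeR adjusted p = 0.129 and 0.369). The table used for names gives no symbol for the IDs printed here.

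The 10 most abundant genes of a library took 6.05% ± 0.0681 of the counts in liquid and 6.35% ± 0.554 in solid culture (mean ± SD, n = 3), a difference smaller than the spread in solid culture (exact permutation test, two-sided p = 0.7, where 0.1 is the smallest possible with 3 against 3). Without the third solid library, the highest at 6.98%, the difference of 0.295 percentage points became -0.025. The 50 most abundant genes took 17.3% ± 0.329 in liquid and 14.5% ± 0.757 in solid culture (exact permutation p = 0.1). The ribosomal RNA rows took 0.998% ± 0.293 and 1.64% ± 0.56 (exact permutation p = 0.2). Genes with at least 1 count numbered 11141 ± 48.9 in liquid and 11494 ± 16.8 in solid culture (exact permutation p = 0.1), and 11124 ± 47.3 and 11488 ± 16.5 with all libraries thinned to 18129454 counts.

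Genes that changed lay next to genes that changed the same way. Of 9978 pairs of adjacent tested genes, 2547 (25.5%) had both members changed in the same direction, against 17.5% on average and at most 18.4% in 1000 permutations of gene order within chromosomes (permutation p = 0.001, the smallest they can give). There were 96 runs of 5 or more consecutive tested genes that all changed the same way by at least 2-fold, 72 higher and 24 lower in solid culture, against a permuted mean of 6.61 and a highest of 18 (permutation p = 0.001, the smallest they can give). The siderophore genes sidJ, sidH, sidD and mirD lay in 1 run of 11 lower genes with a median log2 fold change of -5.05. The pigment gene ayg1 lay in a run of 8 higher genes, aspf1 in a run of 12, and hmgX, hmgA, fahA and maiA in a run of 5. Gene order came from the ASM18445v3 table, which may not be the assembly used for the counts.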

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

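For the genes with 0 counts, the tests of adjacent genes and of a minimum length were chosen after the result was seen. In the FPKM table, which the gene tests do not use, 30 genes had a mean of at least 10 FPKM while the count tables gave them 0 counts in every library, a signal in data outside the main measurement. The largest was AO090701000867, at 0.894 ± 0.159 FPKM in liquid and 914.2 ± 136 FPKM in solid culture (mean ± SD, n = 3), and it lies inside a run of 11 genes higher in solid culture. The genes dbp3, cia1 and erg12 are among the 30, so the ribosome biogenesis and ergosterol lists lack a member each.

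Both sets of values come from the authors' processing, and no biological explanation was tested. A minimum length for counting is argued against: of 138 other genes shorter than the shortest of the 28 with a known length, at 405 bp, 64 had at least 10 counts in every library, and the longest of the 28 has 3978 bp. The bound of 100 first set for this test was wrong, since a minimum length forbids any such gene. Whether shorter genes were missed more often remains open, as the median length of 846.5 bp, at percentile 24.2 of the others, lay between the planned bounds. Reads shared with an adjacent gene and left out of both would lower the neighbours' counts against their FPKM. Among neighbours with counts, the difference of medians was 0.15 in log2, with a bootstrap 95% interval of 0.007 to 0.316, in the other direction. Neighbours with 0 counts in every library were left out, so a neighbour that lost all its reads could not enter. AO090011000717 and AO090011000718, with consecutive IDs, are both among these genes with 0 counts. For such genes this explanation stays open. Overlapping genes remain open too: 0% of the 28 genes that could be checked overlap another gene in the ASM18445v3 table (Fisher's exact p = 1), but that table lists overlap for only 13 of 11481 others and lacks 583 of the counted genes, so the planned test is void. An annotation that differs between the count and FPKM steps was not tested.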

How the results depend on the processing

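The alternatives without ribosomal RNA rows and, for lists, without the 50 most abundant genes in TMM were chosen after seeing the data. The count of 6204 changed genes stayed within 1.5 times of itself under other scalings, filters and tests, from 4458 with at least 10 CPM in 3 libraries, where fewer genes are tested, to 6556 with the DESeq2 Wald test. Requiring 2-fold gave 4033 changed and 1643 lower, and glmTreat against 2-fold gave 2991 changed, 1915 higher and 1076 lower, by the construction of those thresholds. Leaving out each library gave 5348 to 6081 changed, 2887 to 3207 higher and 2441 to 2874 lower genes. Of the main calls, 2 were reversed and called with the FPKM values and 0 under every other setting. Those still called in the same direction numbered 6180 with DESeq2 size factors, but 5534 with library size alone and 5524 with the FPKM values. Which genes are called therefore depends in part on the scaling. The replicate number as a block gave 5521 changed, 2931 higher and 2590 lower. Libraries of the same number did not deviate together (correlations of -0.175, -0.089 and -0.163), and no library correlated best with its own number. These values give no sign of pairing by number, but deviations from the means of 3 libraries cannot exclude it. Of 102 named genes, 99 passed, but the rule took most of them because they passed here, so this number adds no support. Over 16 settings 1534 of 1630 values kept their side of the threshold, 95 no longer passed, 1 newly passed and 0 reversed with a call. For genes that passed in neither setting, a change of direction was not counted. That stability follows in part from the choice of genes with large or called changes. Camera called 2 lists, 0 with an estimated correlation and 10 with fry, which asks another question, and 2 to 3 with each library left out, heat shock being the added one. The difference in the share of the 10 most abundant genes was 0.295 points, -2.82 for 50 genes and 1.33 for FPKM values, where the cause was not tested, and -0.025 to 0.464 with each library left out. Leaving out overlapping neighbours removed no pair, and neighbours on the same strand only were not run, since the gene table gives no strand. Genes with few counts are limited by depth, so a gene that did not pass is not shown to be unchanged. Simulated 2-fold changes were called in 52% of genes, but with 200 changed genes planted, against 6204 called here. The adjusted threshold is stricter in that setting, so the 52% does not apply to these data.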

Other observations

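Of the genes named after secondary metabolite genes of other fungi, 7 are named after the gliotoxin cluster, with a median log2 fold change of 0.62: 1, gliM, rose by 0.73 ± 0.23, none passed when adjusted over the list alone, and the camera adjusted p was 0.823. The call of gliM was lost without liquid replicate 1, liquid replicate 2, solid replicate 2 or solid replicate 3. All 7 were highest in the second solid library, where gliK had 21.2 CPM against 8.17 and 8.24 CPM in the other solid libraries. Of the other 15, 6 rose and 4 fell (camera adjusted p = 0.941). The gene encD rose by 4.53 ± 0.31, inside a run of 8 higher genes, and fgaCat by 2.17 ± 0.12, while tpcD fell by 2.89 ± 0.23, inside a run of 8 lower genes, and nrps1 fell by 2.29 ± 0.28. The longest runs held 14 genes, all higher in solid culture and none with a symbol, with median log2 fold changes of 7.42 and 3.79.

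All 3 tests of the iron genes were chosen after the result was seen. If iron was scarcer to the cells in the liquid medium, which is a hypothesis, iron-sulphur enzymes would be higher in solid culture, whereas hapX belongs to the list itself and adds no test. The 8 enzymes acoA, sdh2, rip1, lysF, luA, ilv3, ilv3B and ilv3C had a median log2 fold change of 1.46 (camera adjusted p = 0.0316 over 26 lists), a call lost with an estimated correlation (adjusted p = 0.605). With that alternative 0 of the 25 other lists passed either, so this loss decides little. The median is carried by the 5 of amino acid biosynthesis, which all rose, while of the other 3 sdh2 alone passed. Among these 5, ilv3, ilv3B and ilv3C share 1 gene name and may not count as separate enzymes. In that list 2 of the other 15 genes rose, and their median of -0.68 argues against a general rise of the list. Most of the 15 belong to other amino acids, so a rise of the branched-chain genes alone was not tested and stays open. The choice among scalings is argued against by the iron list's median, which was -4.86 or lower under the other 3 scalings. Those scalings moved the all-gene median only between 0.0167 and 0.197, so they could hardly have removed a fall of this size. Iron was not measured and medium and culture form differed together, so iron supply may be a candidate explanation but stays open, as does the form of growth.

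Both tests of the conidiation genes were chosen after the result was seen. The choice among scalings does not account for them: the median log2 fold change of the 12 genes was at least 1.37 under the other 3 scalings, with all-gene medians of 0.0167 to 0.197. As these scalings lie so close, they could hardly have removed a change of this size. A shift of all genes together between the cultures would escape each of them. A larger share of conidiating cells may be a candidate explanation and stays open. The fall of medA, at -1.51 ± 0.17 on the log2 scale, does not decide it, since medA had 567 CPM in liquid culture and a gene expressed in other hyphae too can fall when that share rises. No value here measures expression per cell type.

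With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 6204 genes, 3248 higher and 2956 lower, and the highest of the other splits called 0 in all and 0 in 1 direction, so that 1 split of 10 gave as many. Every other split mixes both cultures in each group, where the difference between cultures becomes spread. A count of 0 there could be foreseen and adds no support. For lists, the real split moved 2 and the highest other split 7, and 8 of the 10 splits, the real one included, moved at least 2. The number of lists moved at the preset correlation therefore does not set the real split apart.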
